A study of Sporobolus alterniflorus and Setaria viridis with 12 samples.

How the data were processed

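Mature leaf RNA of Setaria viridis and Spartina alterniflora was extracted with a PureLink RNA kit and sequenced as paired-end Illumina reads, per the labels' protocols. Groups were taken from the sample titles: control and salt for each species, with 3 libraries per group. The authors deposited 1 table of FPKM values with 2 decimals, for 15218 gene IDs and 12 libraries, per the file headers. RSEM and edgeR are named, without role or version, per the submitters' processing notes. The aligner, the reference sequence, the genome build and any filter are not given in the sources used here, nor is the way in which S. alterniflora reads came to be assigned to Setaria IDs. Genes whose reads are shared with near-identical copies are uncertain for that reason. If S. alterniflora reads were placed on gene models of another species, divergent genes would read low in that species. The columns name the group and a letter, A to C, not the replicate number of the labels, so columns were assigned to groups and not to single samples. Columns named 50 for S. viridis and 250 for S. alterniflora were assigned by species and treatment. A swap of the species prefixes would also give this mismatch with the protocol's doses, which the files used here cannot settle.

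FPKM is not a count, so no count model was used. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test of eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), over genes with a mean of at least 1 FPKM across the libraries of each fit. Each salt comparison used the 6 libraries of its species, the interaction all 12, and the species comparison the 6 control libraries. Those tests, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, with no ID paired with a name, at most 2 IDs that were higher and 2 that were lower are named per comparison. These are the largest in log2 fold change among called genes, for the salt comparisons only among those whose groups do not overlap. The rule's 16 gene lists could not be used because 0 IDs are paired with a name. Read steps and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The exact permutation tests compared all splits of 3 against 3 libraries. No library was left out of the main fits. A fold change on this scale understates the change of low genes, and a value of 0 is given as listed at 0.

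The labels do not say that libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical. Read totals were not used here. In S. alterniflora, ratios of values between 0.15 and 0.8 FPKM piled up at 1 ratio in each of 15 library pairs, 3.05 to 12.07 times above neighbouring ratios, as steps of 1 read would give, and those ratios were 0.923 to 1.221. If the steps are single reads, the 6 libraries differ in depth by no more than that. Such ratios compare libraries and do not give the depth itself. In S. viridis only 7 of 15 pairs reached 2 times the neighbouring ratios, so there the relative depth is unknown too. Each fit was tested on simulated values with 200 changed genes, 100 at each size, drawn with the residual spread of the real genes. It recovered 20% of 2-fold and 69% of 4-fold changes for S. viridis salt among 11266 genes, with 9 false calls. It recovered 0% and 45% for S. alterniflora salt among 11330 genes, with 2 false calls. For the interaction, 1% and 27% were recovered among 12529 genes with 3 false calls. For the species comparison, 26% and 72% were recovered among 12134 genes with 6 false calls. Except for S. alterniflora salt, the real fits called far more than 200 genes. The adjusted threshold loosens as more genes change, so the simulated shares do not give the recovery of those real fits.

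The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, upper quartile scaling, median centring, limma without trend, 1 fit over all 12 libraries and each library left out in turn. The column letter as a block, and the overlaps between species without single libraries, were added after seeing the data.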

Results

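RNA from mature leaves was sequenced for 2 salt-treated grasses, Setaria viridis, a small C4 grass used as a laboratory model, and Spartina alterniflora, a salt marsh cordgrass that the labels list under its current name Sporobolus alterniflorus. Each species had a control group and a group treated with NaCl, with 3 libraries per group and 12 libraries in all. The title of the series sets the sensitivity of S. viridis to salt against that of S. alterniflora, and the comparisons below follow that question. The treatment protocol in the labels gives 250 mM NaCl for S. viridis and 50 mM for S. alterniflora, whereas the column names of the deposited table carry 50 for S. viridis and 250 for S. alterniflora. The 2 sources could not be reconciled, so the dose of either species is uncertain, and by both sources dose and species differ together. Species prefixes swapped in the column names would give the same mismatch, in which case every value below given for one species would belong to the other. Species are named here as the column names give them. The libraries of a group are called A, B and C after the letters in those column names.

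The table gave FPKM (fragments assigned to a gene, scaled by gene length and library size) for 15218 Setaria gene IDs in both species. The files pair 0 of these IDs with a gene name, so genes are given by ID, at most 2 that were higher and 2 that were lower per comparison, and no pathway is named. FPKM keeps no read total, so the depth behind each value is unknown in both species. Total FPKM per library ranged from 510410 in S. viridis salt library A to 915944 in S. alterniflora control library C. On average 10745.3 ± 47.5 genes (SD, n = 3) reached 1 FPKM in S. viridis controls and 10699 ± 341.7 under salt, against 10796.7 ± 165.1 and 11093.7 ± 237.6 in S. alterniflora.

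Species separated the libraries along the first principal component, which held 68.33% of the variance of 12529 genes, and the second component held 18.18%. Spearman correlations across all 15218 genes were 0.982 to 0.989 within S. viridis controls and 0.949 to 0.956 within S. viridis salt libraries. They were 0.894 to 0.936 within S. alterniflora controls and 0.854 to 0.928 within its salt libraries. Between salt and control libraries they were 0.772 to 0.879 in S. viridis and 0.799 to 0.909 in S. alterniflora, where they overlapped the range within groups. Between the controls of the 2 species they were 0.496 to 0.516. Genes are not independent replicates, so these values describe the libraries and carry no test.

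**Figure D1:**
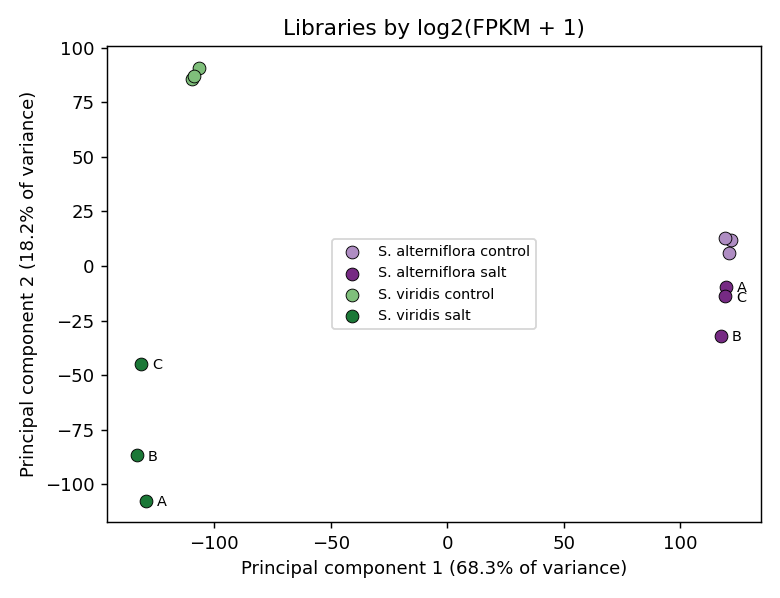
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal components of log2(FPKM + 1), in score units, with 1 point per library and the salt libraries marked by letter. The first component, 68.3% of the variance, parts the species, and the second, 18.2%, parts S. viridis salt from control libraries more widely than those of S. alterniflora.

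Salt changed the levels of 5913 of 11266 tested genes in S. viridis leaves, with 2859 higher and 3054 lower than in controls (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 2218 rose and 2361 fell by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. Sevir.9G447600 rose by 11.39 ± 0.53 (log2 fold change ± SE, adjusted p = 3.46e-05), from 3.72, 0.2 and 0.42 FPKM in control libraries to 5502 ± 1506 FPKM (SD, n = 3) under salt. Sevir.3G165600 rose by 10.03 ± 0.47 (adjusted p = 3.46e-05), from 0.64, 0.18 and a listed 0 FPKM in controls to 1502 ± 931.9 FPKM. Sevir.2G444300 fell by 9.2 ± 0.31 (adjusted p = 2e-05), from 825.8 ± 342 FPKM to 0.3367 ± 0.1739 FPKM. Sevir.2G300400 fell by 9.11 ± 0.74 (adjusted p = 0.000164), from 2572 ± 760.2 FPKM to 5.597 ± 6.461 FPKM. The rule for named genes required each of the 3 salt libraries to lie outside the range of the 3 controls, so that separation is no added evidence. Which direction held more calls depended on the setting: upper quartile scaling gave 2508 higher and 3997 lower, a filter at a mean of 5 FPKM 2312 higher and 2157 lower, and leaving out salt library A 2698 higher and 2442 lower.

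The called share of S. viridis genes was higher among abundant genes, at 47.06% of genes with a mean of 1 to 10 FPKM, 55.04% of those at 10 to 100 FPKM and 69.94% of those at 100 FPKM and above. Among the lowest class 1029 genes rose and 1482 fell, in the middle class 1508 rose and 1245 fell, and among the most abundant 322 rose and 327 fell. Listed at 0 in every control and at 1 FPKM or more in every salt library were 28 genes, 24 of them among those called, and 7 showed the opposite, 5 of them called. The 10 most abundant genes of each library held 14.63% ± 0.372 (SD, n = 3) of total FPKM in controls and 8.511% ± 1.09 under salt, with p = 0.1 by a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow. Salt library C lay nearer to the controls than the other salt libraries on the first component within the species, with a score of -49.7 against -111.9 for A and -92.7 for B, where controls were at 82.3 to 87.8. Without library C, 7033 genes were called. Without control library B, 3907 genes were called.

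In S. alterniflora leaves, salt changed 184 of 11330 tested genes, with 162 higher and 22 lower than in controls (limma, adjusted p under 0.05), all by at least 2-fold on the same scale. Sevir.4G111600 rose by 8.13 ± 1 (log2 fold change ± SE, adjusted p = 0.0146), from 7.62 ± 11.2 FPKM (SD, n = 3) to 1558 ± 966.5 FPKM. Sevir.5G417100 rose by 5.2 ± 0.8 (adjusted p = 0.0287), from 19.2 ± 18.88 FPKM to 614.8 ± 403.7 FPKM. Sevir.3G270500 fell by 5.25 ± 0.85 (adjusted p = 0.0335), from 381.8 ± 80.6 FPKM to 15.94 ± 19.05 FPKM. Sevir.3G135700 fell by 4.6 ± 0.49 (adjusted p = 0.00943), from 86.61 ± 42.21 FPKM to 2.583 ± 1.506 FPKM. That the 3 salt libraries of these 4 genes lay outside the range of the controls was again required by the rule.

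The genes that rose in S. alterniflora numbered 60 at a mean of 1 to 10 FPKM, 86 at 10 to 100 FPKM and 16 at 100 FPKM and above, and those that fell numbered 9, 11 and 2. Of the 6358, 4388 and 584 genes tested in these classes, 1.085%, 2.211% and 3.082% were called. Genes listed at 0 in every control and at 1 FPKM or more in every salt library numbered 13, 2 of them called, and 2 showed the opposite, 0 of them called by limma. The 10 most abundant genes held 35.02% ± 9.106 of total FPKM (SD, n = 3) in controls and 29.45% ± 2.111 under salt, with p = 0.5 by a two-sided exact permutation test. A single gene took 9.988% of total FPKM in control library C. The number of calls in this species fell when single libraries were left out: without control library A limma called 0 genes, with 1099 at an unadjusted p under 0.05 against 1670 with all libraries, and the smallest adjusted p was 0.0699. Counts were 67 without control library B, 49 without control library C, 116 without salt library A, 154 without salt library B and 35 without salt library C. A fit over all 12 libraries, which pools the spread of both species, called 526 genes, 176 of the 184 among them. The self-test on simulated values recovered 45% of 4-fold changes and 0% of 2-fold changes at this spread, so a gene not called here is not shown to be unchanged.

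**Figure D2:**
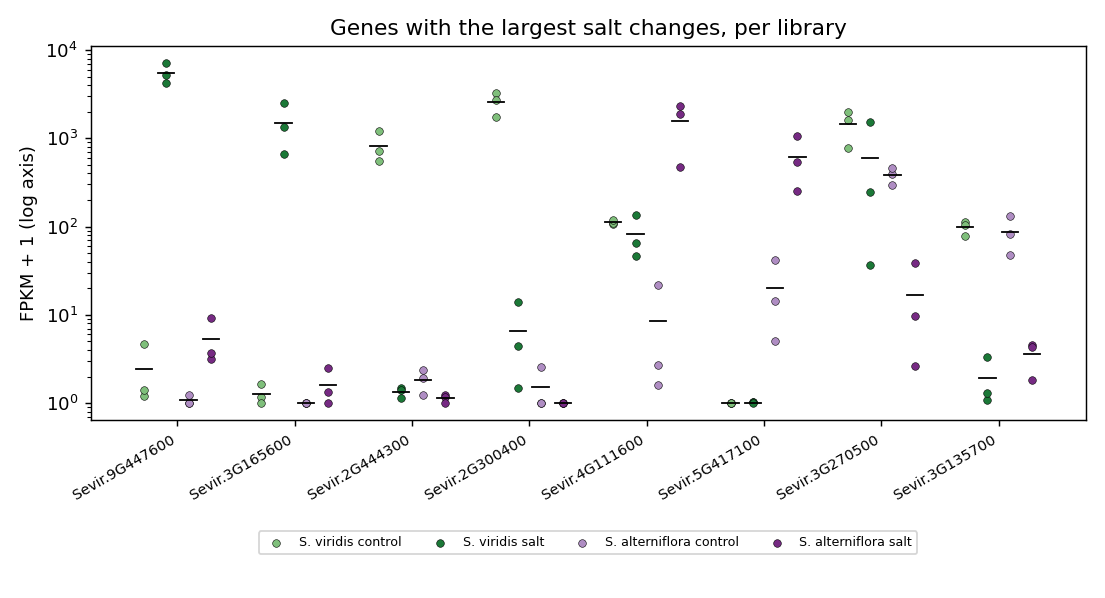
FPKM + 1 on a log axis for the 8 genes named under the salt comparisons (horizontal axis), with 1 point per library, 3 per group, and a bar at the group mean. Sevir.9G447600 lies at 4179.62 to 7141.27 FPKM in S. viridis salt libraries and at 3.72 or less in its controls, and Sevir.4G111600 at 475.34 to 2334.38 FPKM in S. alterniflora salt libraries and at 20.54 or less in its controls.

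Whether the salt effect differed between the species was tested as an interaction over all 12 libraries, the S. viridis effect minus the S. alterniflora effect. It differed for 3029 of 12529 tested genes, with 1346 higher and 1683 lower in S. viridis (limma, adjusted p under 0.05). The difference was 9.46 ± 0.63 (log2 ± SE, adjusted p = 1.44e-05) for Sevir.3G165600, which was listed at 0 in all 3 S. alterniflora controls and at 0, 1.49 and 0.33 FPKM in its salt libraries. For Sevir.9G447600 it was 9.24 ± 0.72 (adjusted p = 2.07e-05), and 7.99 with a pseudocount of 0.1. In S. alterniflora this gene was at 0, 0.23 and 0 FPKM in controls and at 4.367 ± 3.392 FPKM (SD, n = 3) under salt. Its salt effect there was 2.15 ± 0.47 (limma, adjusted p = 0.0802). For Sevir.4G111600 it was -8.73 ± 1.19 (adjusted p = 0.000477), with S. viridis at 111.2 ± 6.6 FPKM in controls and 81.05 ± 47.12 under salt. For Sevir.2G300400 it was -8.66 ± 0.9 (adjusted p = 9.23e-05), a gene at 0, 0 and 1.54 FPKM in S. alterniflora controls and listed at 0 in all 3 of its salt libraries. Sevir.2G300400 thus had a level in S. alterniflora controls too low for a fall of that size to be measured there.

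Of the 3029 genes, 2656 had been called in S. viridis but not in S. alterniflora, and 71 in S. alterniflora but not in S. viridis. Another 37 had been called in both, 8 of them in opposite directions, and 265 in neither. Genes under the filter in a species were not tested there and count as not called, such as Sevir.3G165600 in S. alterniflora. The 2656 are therefore not all genes that were tested in S. alterniflora. Sevir.3G135700 fell by 4.6 ± 0.49 in S. alterniflora and fell by 5.86 ± 0.43 (adjusted p = 0.000108) in S. viridis, and its interaction did not pass (-1.25 ± 0.7, adjusted p = 0.212). The interaction call count was 1966 without S. viridis control library B. The difference in dose is part of this contrast. Its fit pools the spread of both species, which differed in the separate fits (median residual SD 0.335 in S. viridis and 0.442 in S. alterniflora). Other regroupings of the S. alterniflora libraries alone gave 2366 to 4226 calls, so the count is not specific to their real grouping.

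Over the 9384 genes tested in both species, the salt effects correlated across genes with Pearson's r = 0.335 and Spearman's rho = 0.275, and 58.3% had the same sign. Genes that rose in S. viridis had a median S. alterniflora effect of 0.31 (log2), and genes that fell one of -0.08. Among genes called in S. alterniflora, 83.3% had the same sign in S. viridis. For the far larger set called in S. viridis, 62.6% had the same sign in S. alterniflora. In all, 85 genes rose in both species against 33.6 for independent lists of the same sizes (Fisher's exact test, two-sided, adjusted over 4 overlaps, p = 2.05e-20). Genes that fell in both numbered 7 against 4.1 (adjusted p = 0.188). Genes that fell in S. viridis and rose in S. alterniflora numbered 6 against 36.8 (adjusted p = 1.39e-11), and the opposite pattern 2 against 3.7 (adjusted p = 0.385). The 2 comparisons share no libraries, but genes are not independent, so these p-values are too small. Without S. alterniflora control library A all these overlaps were 0, since no gene was then called in that species.

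**Figure D3:**
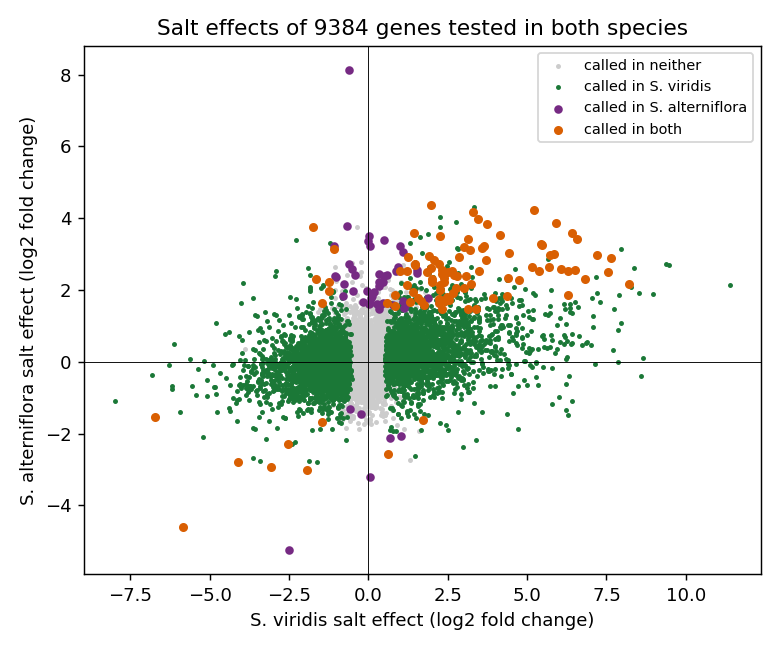
Salt effect (log2 fold change of FPKM + 1) in S. viridis (horizontal) against S. alterniflora (vertical) for 9384 genes tested in both, 1 point per gene, coloured by the species in which it was called. Most of the genes called in both lie at upper right, where 85 rose in both.

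The control groups were set side by side to compare leaf levels without salt. Of 12134 tested genes, 8768 differed, with 4792 higher and 3976 lower in S. viridis (limma, adjusted p under 0.05). With each library centred on its median the split turned to 3989 higher and 5065 lower, so the direction of the excess depended on the scaling. Sevir.5G428700 was higher in S. viridis by 12.18 ± 0.37 (log2 difference ± SE, adjusted p = 8.43e-07), at 6258 ± 1494 FPKM (SD, n = 3) against 0, 1.32 and 0 FPKM in the S. alterniflora libraries. Sevir.2G441600 was higher by 11.04 ± 0.22 (adjusted p = 4.45e-07), at 2612 ± 448.1 FPKM against 0.49, 0.24 and 0 FPKM. Sevir.5G271000 was lower in S. viridis, with a difference of -9.53 ± 0.24 (adjusted p = 4.67e-07), at 0.6467 ± 0.45 FPKM against 1201 ± 209.1 FPKM. Sevir.1G118400 was lower with a difference of -9.2 ± 0.26 (adjusted p = 6.97e-07), at 0.8433 ± 0.4304 FPKM against 1094 ± 322.9 FPKM.

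Across all libraries, 192 genes were listed at 0 in all 6 S. viridis libraries and at 1 FPKM or more in all 6 of S. alterniflora, and 22 the other way round. How S. alterniflora values were assigned to Setaria IDs is not given in the sources used here. Species, culture and that assignment differ together in this comparison.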

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

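The spread test for the count of calls, the floor and rank tests for S. viridis library C, and the rank and S. viridis effect tests for S. alterniflora library B were chosen after the results were seen, as was the enumeration of the 20 regroupings below.

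Salt effects differed between the species by the interaction test for 3029 genes. Among named genes the S. viridis minus S. alterniflora difference was 9.24 for Sevir.9G447600, 9.46 for Sevir.3G165600, -8.56 for Sevir.2G444300, -8.66 for Sevir.2G300400, -8.73 for Sevir.4G111600 and -5.18 for Sevir.5G417100 (log2). Some of these genes were near 0 in the other species. Sevir.2G444300 was at 1.37, 0.94 and 0.23 FPKM and Sevir.2G300400 at 0, 0 and 1.54 FPKM in S. alterniflora controls, so a fall of this size could not be measured there, and Sevir.5G417100 was at 0.02 FPKM or less in all 6 S. viridis libraries. No group had 4 or more libraries, so no outlier test was run within a group. Libraries that stood apart are weighed below.

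In 100 splits of the libraries within species, the real one included, 4 gave as many interaction calls as the real 3029, the highest other being 4226. The share depends on the draw: an earlier draw of 100 with another seed gave 6, and by calculation 0.18 of such draws hold 5 or more. The drawn splits that parted the S. viridis groups gave at most 22 calls, but such splits also remove the S. viridis salt effect. A share under 0.05 here therefore cannot exclude chance for the difference between species. Nor can it for the S. viridis groups, since 20 of all 200 splits keep those groups, which is not under 0.05. Over all 200 splits the share would be 0.03 if no undrawn split that parts the S. viridis groups is as large, which was not computed. When the S. viridis groups were kept and only S. alterniflora libraries regrouped, 6 of all 20 regroupings, the real one included, gave as many calls. Counts in all the regroupings other than the real one were 2366 to 4226, so the count is not specific to the real S. alterniflora grouping. For S. viridis salt, 1 of 10 splits gave as many calls (real 5913, highest other 1), for S. alterniflora salt 1 of 10 (184, highest other 1), and for the species comparison 1 of 10 (8768, highest other 0). With 10 splits a share under 0.05 cannot be reached.

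The first pattern is the larger number of salt calls in S. viridis. A larger spread between S. alterniflora libraries alone is argued against by the SD of salt effects after subtracting their error. That SD was 1.93 in S. viridis and 0.653 in S. alterniflora over 1737 genes of 20 FPKM or more in both, a ratio of 2.96. The bootstrap SE of 0.18 resampled genes and not libraries, so it leaves out the variation between libraries. Among the 309 genes of 100 FPKM or more in both, 209 were called in S. viridis and 9 in S. alterniflora, a ratio of 23.2. That ratio cannot decide on lower depth, since the adjusted p was taken over all tested genes of each species, low ones included. Over the 1737 genes above, the median residual SD between libraries was 0.383 in S. viridis and 0.405 in S. alterniflora. Values this close argue against a larger spread from lower depth as the sole cause for those genes. The residual SD holds every difference between libraries of a group, such as that of S. viridis salt library C, so it does not measure depth. Over all tested genes the medians were 0.335 in S. viridis and 0.442 in S. alterniflora, so lower depth is not argued against outside those genes. The explanation by 1 divergent S. alterniflora library is argued against by the highest count on leaving out any 1 of its libraries, 154. Leaving out a library also leaves fewer to test with, though S. viridis fits with 1 library left out still called 3907 to 7033 genes. A species difference in the salt response and a difference in dose remain open and untested, since species and dose differ together and the sources conflict on the doses, and so do the assignment of S. alterniflora values to Setaria IDs and a swap of the species prefixes in the column names, which would exchange the species throughout. Genes listed at 0 in all 6 libraries of one species and at 1 FPKM or more in all 6 of the other numbered 192 for S. viridis at 0 and 22 for S. alterniflora at 0, the opposite of the order that reads of a distant species placed on Setaria gene models would give, which settles neither point, since how the values were assigned is not given in the sources used here.

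The second pattern is S. viridis salt library C, which lay at 0.693 on the axis from the control mean (0) to the mean of salt libraries A and B (1). Scaling is argued against by ranks, which no library factor can change: the lowest rank correlation of C with a control exceeded the highest of A and B by 0.114 over the 11266 tested genes (0.744 against 0.629; over all 15218 genes 0.871 against 0.816), whereas the position after upper quartile scaling, also 0.693, decides nothing, since a shift of 1 log2 unit in all genes of C would move it by only -0.018. For control RNA mixed into C, the share needed was 0.167 from genes that fell and 0.498 from genes that rose, a difference of 0.331, beyond the bound set for it, but the same difference was 0.325 for library B against A and -0.0589 for A against B, so a gap of this size also arose between the other salt libraries in 1 of 2 cases and was not taken to decide. Over 16 genes of 100 FPKM or more in controls and at least 32 times lower in A and B, the 10th percentile of C over the control mean was 0.00184 and 10 of 16 lay under 0.05, which argues against control RNA at a share of 0.167, while a much smaller share remains open. A plant that responded less remains open, and no biological explanation was tested.

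The third pattern is S. alterniflora salt library B, which stood apart from A and C. Scaling is argued against by rank correlations, which no library factor can change, where A with C exceeded the higher value of B by 0.057. Low depth is argued against by genes of 20 FPKM or more, where A with C was at 0.924 and B at 0.792 and 0.826, a gap of 0.097. The deviation of B from A and C correlated with the S. viridis salt effect across genes at 0.151, consistent with a larger part of the change seen in S. viridis, but control library B, which had no salt, gave 0.093. The evidence for that reading is weak, and other differences between plants or libraries remain open.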

How the results depend on the processing

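The block by column letter and the overlaps without single libraries were added after seeing the data. The S. viridis count stayed within 1.5 times of 5913 except in 1 case, and ranged from 3907 (without control library B) to 7033 (without salt library C) when 1 library was left out. The S. alterniflora count of 184 became 105 with the column letter as a block and 526 in 1 fit over all 12 libraries, and ranged from 0 (without control library A) to 154 (without salt library B). The interaction count of 3029 ranged from 1966 (without S. viridis control library B) to 3917 (without S. viridis salt library C). Leaving out a library also leaves fewer libraries to test with; the cause was not tested otherwise. The species count of 8768 stayed within 1.5 times under every alternative tried. Upper quartile scaling moved the median effect of all genes from -0.116 to -0.273 in S. viridis, from 0.064 to -0.058 in S. alterniflora and from 0.161 to -0.126 between species, and centring moved the last to -0.228 and its split to 3989 higher and 5065 lower.

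Of the values for named genes, correlation and overlaps under the alternatives, 252 kept their direction and call or moved little, and 0 reversed. 13 lost their call, all S. alterniflora genes with 1 library left out, with adjusted p of 0.0556 to 0.145 by limma, while their log2 fold changes stayed at 81.7% to 103.2% of those with all libraries. The 3 overlaps of 85, 7 and 6 genes went to 0 without S. alterniflora control library A. Genes that rose in both numbered 82 without S. viridis salt library C and 67 without S. alterniflora salt library B. The correlation of salt effects was 0.287 to 0.354 over left-out libraries (jackknife SE 0.054).

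No paired analysis was possible because the columns carry letters that are not tied to the replicate numbers of the labels. A block by letter could be fitted, though it is no pairing the labels give, and called 5519 genes in S. viridis, 105 in S. alterniflora, 2587 for the interaction and 8456 between species. Libraries with the same letter did not deviate together, with correlations of -0.101 to 0.059 over 18 pairs. The block by replicate number and all gene list tests were therefore not run, the latter because no ID is paired with a name. Depth is unknown in both species and limits low values to an unknown degree.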

Other observations

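The test of control levels was chosen in its present form after the results were seen; the test of neighbouring genes was planned.

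Salt effects of genes with consecutive IDs were correlated in both species. Pearson's r across 4529 pairs was 0.127 in S. viridis (highest of 1000 shuffles within the chromosome number of the ID 0.043) and 0.081 across 4297 pairs in S. alterniflora (highest shuffle 0.047). At an ID distance of 2 r was 0.056 and 0.037, and at a distance of 10 it was 0.026 and 0.003. A candidate explanation is that neighbouring genes change together, if ID order follows the chromosome. Reads shared between tandem copies would also give such a correlation and were not tested, since no sequence was used here.

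A hypothesis was that S. alterniflora controls already hold the levels that S. viridis reaches under salt. It predicts, at matched S. viridis control level, higher S. alterniflora control levels for genes that rose in S. viridis and lower ones for genes that fell. In a first version, matched on the same control libraries that entered the calls, the difference from uncalled genes was 0 for genes that rose (permutation p = 0.98 over 1000 shuffles) and -0.18 for genes that fell (permutation p = 0.01). Because those controls served both steps, the test was changed after that result to match on a control library left out of the calling fit. It then gave -0.03 (log2; SD over 300 shuffles 0.03, permutation p = 0.39) for genes that rose and -0.12 (SD 0.043, permutation p = 0.013) for genes that fell. Neither version showed the difference predicted for genes that rose. The difference for genes that fell had the predicted sign in both versions. It was small beside 1.46, the median absolute log2 fold change of all genes called in S. viridis. The hypothesis predicted both differences, so these values do not bear it out as stated. The shuffle p-values treat genes as independent.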
